A study of Mus musculus with 4 samples.

How the data were processed

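H3K27ac, the acetylation of lysine 27 on histone H3 that marks active promoters and enhancers, had been profiled by chromatin immunoprecipitation and sequencing in the gastrocnemius, a large calf muscle of the hindlimb. Per the labels, the tissue came from female adult mice of the hybrid strain B6CASTF1/J aged 2 months, and each of the 2 biological replicates was a pool of 2 tissue samples. Each replicate had 2 technical replicate libraries, 4 libraries in all, and there was 1 group, so no groups of samples were compared. Per the deposited descriptions of the libraries, the technical replicates of a biological replicate shared 1 alignment, so they could not be told apart here and do not count in n.

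The authors deposited 4 peak lists on the mouse assembly mm10, in the narrowPeak format. Per those deposited descriptions, 1 list was made from the alignments of replicate 1, 1 from replicate 2 and 1 from both replicates pooled. The last, called the replicated list, was made from both replicates, and not all of its regions were shared with both single-replicate lists. The first 3 are of the type called pseudoreplicated. Which list belonged to which replicate was learned from the deposited descriptions after the design of the tests had been fixed; until then these lists were told apart only by length. The aligner, the peak caller, its thresholds and the filters are not given in the sources used here. The control library was not analysed here.

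Each peak has a signal value, deposited by the authors in the signal column of the format, and what that value is relative to is not given in the sources used here. It was compared only within a list. There it served to describe and rank regions, as an alternative to the covered length near gene starts, and to compare promoters of X with those of the autosomes. The authors also deposited for each peak a p-value and a q-value as −log10, and the distance of the summit from the start of the peak. The deposited lists hold no read counts, so the depth of each library is unknown and no interval that needs depth is given. A longer list can come from deeper sequencing, from stronger enrichment or from more acetylated chromatin, and list length alone cannot separate these.

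Overlapping peaks of a list were to be merged into regions, which changed no list, so regions and peaks are the same here. The lists were checked against the GRCm38 sequence, the assembly named mm10 in the deposited lists: no peak ran past a chromosome end, and 0 summits lay on an unknown base. Genes came from the GENCODE mouse annotation, release M21, basic set: 21644 protein-coding genes on the 19 autosomes and X, with 41129 transcript starts. All coordinates are mm10 and counted from 1.

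A region counted as shared with another list where at least 50% of the shorter of both regions overlapped. The share expected by chance came from 1000 circular shifts of the regions, 1 random shift per chromosome, whose smallest possible p is 0.001. Regions were placed in order into promoter (within 1000 bp of a protein-coding transcript start), exon, intron or intergenic sequence. A gene had a promoter region where a region lay within 1000 bp of any of its starts. Its acetylated length was the number of base pairs covered by regions within 5000 bp to each side of a start, 10000 bp at most, taking the start with the largest value. Regions at most 12500 bp apart were stitched into domains, domains were ranked by the base pairs covered, and long domains were those past the point where the ranked curve, scaled to 1 on both axes, had slope 1.

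30 gene lists (pathways, fibre types, cell types and controls) were fixed before the data were examined. Genes are not replicates, so a list's number of promoter regions, median acetylated length and number of genes in long domains were each set against 10000 random lists of as many protein-coding genes. The percentile reached, with ties counted at equal shares, describes these peak lists and is not a p-value. A list was called above or below where it lay outside the central 95% of random lists, from percentile 2.5 to 97.5. The mean acetylated length of members was compared between lists in 3 comparisons by a two-sided permutation test over genes with 100000 resamples, whose smallest possible p is 1e-05, with Benjamini-Hochberg adjustment over the 3. These p-values describe the lists of genes in this peak list, and not variation between animals.

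Motifs were searched as fixed consensus strings on both strands within 250 bp of the summits of distal regions, which are those outside promoters. The share of windows with a match was divided by the share in windows of 500 bp centred 5 kb away that overlapped no region, with an interval covering the central 95% of 1000 bootstrap draws of regions. The 16 motifs were fixed before the data were examined. Regions per Mb were counted for each chromosome.

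The genes named in the text follow a rule fixed before the data were examined: genes with a start in the 10 longest domains, genes within 1 kb of the 10 regions of highest signal value, the 3 members of each list with the largest acetylated length and up to 3 members without a promoter region in the order of the list, and the members of the fast, slow, cardiac, hindlimb and anterior lists freely. Genes outside the rule are said to be so where they appear. Some genes stand in more than 1 list, among them Des, Egr1, Fabp4, Eno3 and Atp2a1. Some members of the lists, counted in all values, and 1 motif are not reported here by name.

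Alternatives fixed in advance were the pooled list or each replicate's list in place of the replicated list, peaks with −log10 q of at least 5, other overlap rules (1 bp, or 50% of both regions), ranking by width, promoters of 500 or 2500 bp, the 5′ end of the gene model alone, a window of 25 kb, the highest signal value in place of the covered length, random lists matched on gene span or promoter CpG count, other stitching and ranking of domains, shuffled sequence as motif background, and motif windows within 100 bp of the summit. Chosen after the data were seen were circular shifts with assembly gaps removed, 200 of them, and random lists drawn from genes with a promoter region.

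The methods were tested on simulated data first. The overlap step found 100% of 3788 planted shared regions, and 5% of 200 unplanted gene lists fell outside the central 95%. For lists of the sizes of the fast and slow lists, the permutation test called 5.5% of 200 equal pairs and 82.5% of 200 pairs that differed by 1 SD. A motif planted at a ratio of 4.20 over 20000 windows was recovered at 4.19. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and numba 0.67.0, and plots were drawn with matplotlib 3.10.9.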

Results

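H3K27ac was profiled in the gastrocnemius, a calf muscle made mostly of fast-twitch fibres, from female adult mice. The series held 4 libraries, 2 technical replicates from each of 2 biological replicates, and each biological replicate was a pool of 2 tissue samples. The measurements were 4 deposited peak lists on mm10, 1 for each replicate, 1 for the pooled replicates and 1 replicated list drawn from both. There was 1 group of samples, so the spread between replicates was read from the 2 lists of single replicates. Read depth is unknown.

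Acetylated chromatin covered 118.0 Mb of the genome (4.33%) in the 84452 regions of the replicated list, with a median width of 860 bp (quartiles 461 and 1719 bp). The strongest regions lay at the starts of Efcab2 (1:178404830-178407552, signal value 77.04), Nfyc, which encodes a subunit of the CCAAT-binding factor NF-Y (4:120824120-120826698, 76.3), and Klf7, a Krüppel-like transcription factor (1:64116447-64123317, 75.0). Next came the starts of Atp6v0c, a subunit of the vacuolar proton pump (17:24167842-24171079, 74.7), and Actg1, the cytoplasmic gamma actin (11:120347230-120355121, 73.3). Klf9, a Krüppel-like factor induced by glucocorticoids (19:23131146-23154037, 72.7), Rfx3, a regulator of ciliary genes (19:28009482-28012689, 72.5), Kmt5b, a histone H4 methyltransferase (19:3766839-3771050, 72.0), and Picalm, an endocytic adaptor (7:90128031-90137298, 71.6), were also among the 10 highest. The remaining region of these 10 (4:141544328-141548393, 73.2) lay in no protein-coding gene and within 1 kb of no annotated start. The signal values are the authors' own and rank regions within the list; 71502 peaks of the replicated list (84.7%) had a −log10 q of at least 5, and 165 had a q above 0.05.

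The strongest regions were found in both replicates, and the weakest regions of replicate 2 were mostly not shared with replicate 1. Replicate 1 had 70953 regions covering 85.1 Mb and replicate 2 had 86937 covering 117.8 Mb, against 91329 covering 120.8 Mb for the pooled list. Of the replicate 1 regions, 92.5% (65642) were shared with replicate 2, against 6.09% on average and 8.31% at most for shifted regions. Of the replicate 2 regions, 62.5% (54306) were shared with replicate 1, against 4.78% on average and 6.49% at most for shifted regions. With each list split by signal value into 10 bins of equal number, the shared percentage in replicate 2 was 15.2% in the lowest bin, 55.7% in the fifth, 92.6% in the seventh and 99.99% in the highest. In replicate 1 it went from 73.3% in the lowest bin to 100% in the highest. Of the replicated list, 92.4% (78003 regions) had identical bounds in the pooled list, and 63.3% (53489) were shared with both single replicates. In a permutation test by circular shifts, every comparison between lists reached p = 0.001, the smallest that 1000 shifts can give. The lists were made from overlapping sets of reads except for those of the single replicates, so only that pair compares separate samples. When 50% of both regions had to overlap, the shares fell to 57.3% of replicate 1 and 46.8% of replicate 2.

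**Figure D1:**
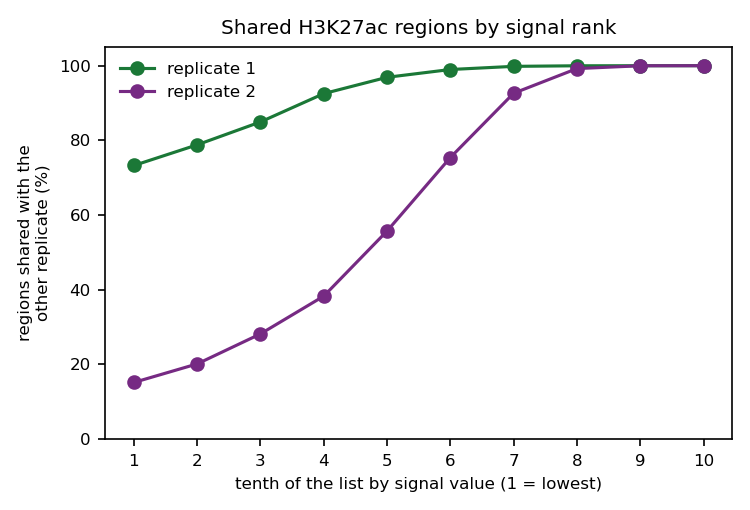
Percentage of H3K27ac regions shared with the other replicate (vertical axis) in 10 bins of each list's own signal value, 1 being the lowest (horizontal axis). Each point is 1 bin of the list of replicate 1 or replicate 2; in replicate 2 the percentage went from 15.2% to 99.99%, and in replicate 1 from 73.3% to 100%.

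Gene starts held far more acetylation than their share of the genome, yet most acetylated sequence was distal. Promoters took 17.97% of the regions (15174 of 84450 on the autosomes and X), against 3.46% for shifted regions (range 3.01% to 3.90%), a 5.20-fold excess. Introns took 43.7% against 30.5%, and exons took 9.46% against 8.10%. Intergenic sequence took 28.9% against 57.9%. Each of these differed from the shifted regions at p = 0.001 in the same permutation test, the smallest possible. Promoter regions were wider, with a median of 1748 bp (quartiles 969 and 2838), than the 69276 distal regions, with a median of 741 bp (426 and 1435). Their median signal value was 21.8 against 4.25. Any base within 1000 bp of a start placed a region among promoters, so wide regions were likelier to fall there. Widths of shifted regions were not computed, so the part of the width difference due to this rule is unknown. Distal regions still made up 69.2% of the covered base pairs, 81.6 Mb. In the single replicates promoters took 21.2% of replicate 1 regions and 17.6% of replicate 2 regions.

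Of 21644 protein-coding genes, 13245 (61.2%) had a promoter region. Both replicates had one at 12687 genes, replicate 1 alone at 57 and replicate 2 alone at 538. The median gene had 1469 acetylated bp of the 10000 bp around its start, and 85 genes were acetylated over the whole window.

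The genes of fast-twitch fibres were the most widely acetylated of all 30 gene lists. All 20 fast genes had a promoter region in both replicates, and their median acetylated length was 9461 bp (8660 bp in replicate 1 and 9313.5 bp in replicate 2). Myh4, the myosin heavy chain of the fastest IIb fibres (11:67238029-67260446), Myl1, a fast myosin light chain (1:66924295-66945404), Tnnt3, fast troponin T (7:142498836-142516009), and Atp2a1, the calcium pump of fast fibres (7:126445858-126463108), were acetylated over all 10000 bp. So was Eno3, the muscle enolase (11:70657202-70662513). Tnnc2 and Tnni2, the other fast troponin subunits, had 9681 and 9659 bp, Mylpf, the fast regulatory light chain, had 9463 bp, and Pvalb, the calcium buffer parvalbumin, had 9226 bp. The lowest were Myh2, the myosin of IIa fibres, with 4308 bp, Pfkm, muscle phosphofructokinase, with 5734 bp, and Eya4, a transcriptional coactivator, with 5988 bp.

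Slow-twitch genes were acetylated too, over shorter stretches. All 16 had a promoter region in the replicated list, 14 in replicate 1 and 15 in replicate 2, with a median acetylated length of 4229 bp (2969.5 and 4012.5 bp). Myh7, the slow myosin heavy chain (14:54970684-54994626), had 1648 bp in the replicated list, 0 in replicate 1 and 1418 bp in replicate 2. Its relative Myh7b (2:155611212-155634307) had 432 bp in the replicated list and 0 in each replicate. Myl3 and Myl2, the slow light chains, had 2446 and 2719 bp, Tnni1, slow troponin I, had 2675 bp, and Tnnt1, slow troponin T, had 3383 bp. The longest stretches belonged to Tead1, a transcription factor that binds slow and many other muscle genes (9623 bp), and Sox6, a repressor of slow genes (6961 bp), neither of which encodes a slow contractile protein. Tpm3, slow tropomyosin, had 6388 bp and Mybpc1, slow myosin-binding protein C, had 6199 bp.

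Fast genes averaged 8520.85 ± 1772 bp (SD, n = 20 genes) and slow genes 4335.94 ± 2252 bp (SD, n = 16 genes), a difference of 4184.91 bp (two-sided permutation test, p = 2e-05, adjusted p = 3e-05 over 3 comparisons). The difference was 4696.65 bp with the replicate 1 list and 4449.25 bp with the replicate 2 list. The units of the test are genes, so it compares these lists of genes in this muscle. In the highest signal value near the start, the slow list lay at percentile 39.6 of random lists and so was not above them.

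**Figure D2:**
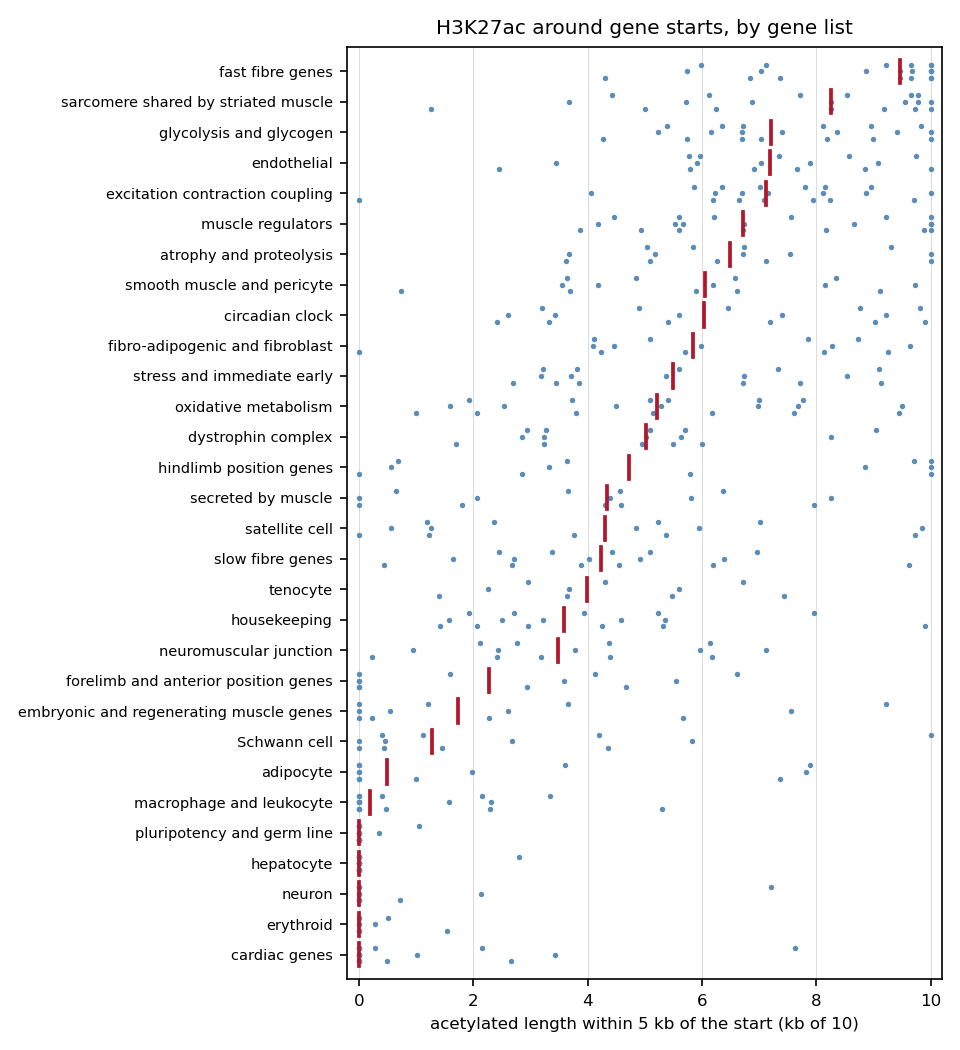
Acetylated length within 5 kb of the gene start (horizontal axis, kb of 10) for the members of the 30 gene lists in the replicated list (vertical axis, ordered by median); each point is a gene and each red bar a list median. Medians went from 0 bp in the cardiac, erythroid, neuron, hepatocyte and pluripotency lists to 9461 bp in the fast list.

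The fast myosin heavy chains lie side by side on chromosome 11, and acetylation was spread unevenly over them. A wide region (67228535-67244908, signal value 31.2) ran across the start of Myh4. The regions at the starts of Myh2 (67171013-67174410, 9.01) and Myh1, the IIx myosin (67200082-67203202, 8.04), were narrower and weaker. In the replicated list the 3 strongest regions of the locus lay between genes, downstream of the embryonic Myh3 and upstream of Myh2: 67103082-67108213 (signal value 34.9), 67109221-67121937 (40.3) and 67122261-67128649 (42.7). A weaker one followed there at 67137507-67145376 (24.0). In replicate 2 the region over the Myh4 start (37.4) was above 1 of these 3 (67109221-67121941, 34.8). No region lay over Myh8, the perinatal myosin (67277124-67308634), or over Myh13, the extraocular myosin (67321658-67371586), and the next region began at 67379749. Myh4 had 9288 acetylated bp in replicate 1 and 10000 in replicate 2, Myh1 had 5185 and 6665, and Myh2 had 2586 and 5043. The locus was drawn, and Myh13 added, after the values were seen.

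**Figure D3:**
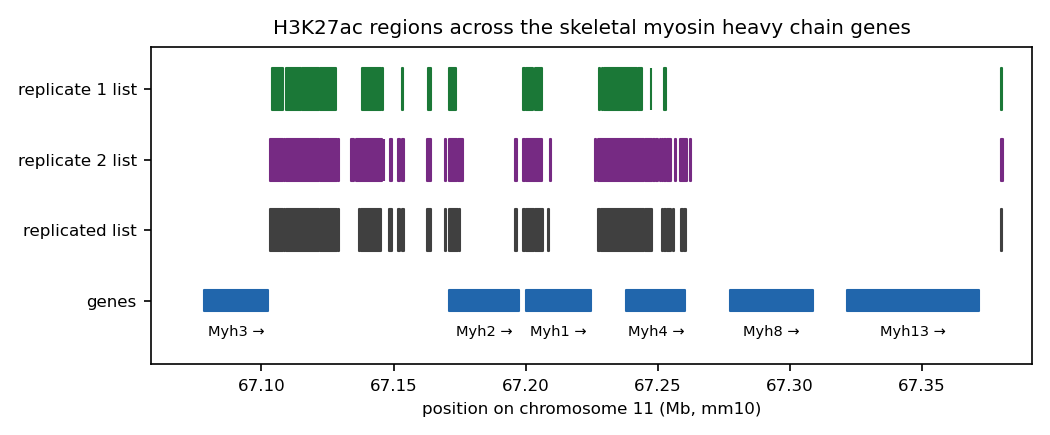
Map of the skeletal myosin heavy chain genes on chromosome 11 (horizontal axis, Mb, mm10), with genes in blue (arrows give the strand) and H3K27ac regions of the replicated list and of each replicate as bars in rows above. The block between Myh3 and Myh2 (67103082-67145376) and the block over the Myh4 start appear in all 3 rows, and Myh8 and Myh13 hold no region.

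The shared machinery of muscle was acetylated in both replicates. All 20 sarcomere genes had a promoter region, with a median acetylated length of 8259.5 bp, led by Ldb3, a Z-disc protein, and Synpo2l, an actin-associated Z-disc protein (10000 bp each), and the giant spring protein gene Ttn (9785 bp). The excitation-contraction coupling genes had 19 of 20 and 7120 bp, led by Atp2a1, Asph (9709 bp), whose products include junctin, and Hrc, a calcium-binding protein of the sarcoplasmic reticulum (8950 bp), and lacking Sln, the inhibitor sarcolipin. All 20 genes of glycolysis and glycogen had a promoter region with a median of 7216 bp, led by Aldoa (10000 bp), Eno3 and Pygm, muscle glycogen phosphorylase (9826 bp). All 20 oxidative genes had one as well, at 5213.5 bp, led by Hadha, of mitochondrial fatty acid oxidation (9493 bp), Mb, myoglobin (9452 bp), and Fabp3, a fatty acid carrier (7764 bp). All 20 muscle regulators had one at 6727.5 bp, with Mef2d, Nfix and Nr4a1, all transcription factors, at 10000 bp. All 15 genes of the dystrophin complex had one at 5028 bp, led by Dag1 (9048 bp) and Sgca (8251 bp).

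These 6 lists lay at percentiles 99.96 to 100 of random lists for promoter regions and at 100 for acetylated length. With the 5′ end of the gene model alone the dystrophin complex had 12 promoter regions and was within random lists (percentile 95.045). A random list of 20 genes had a median of 12 promoter regions and 1444 acetylated bp. The neuromuscular junction genes had 13 of 14 promoter regions (percentile 99.4) and 3485 bp (percentile 99.1), led by Dok7, an activator of the synaptic kinase MuSK (7126 bp), Chrne, the adult acetylcholine receptor subunit (6169 bp), and Prkar1a (6135 bp), and lacking Chrnd. Against random lists of genes that have a promoter region, chosen after the data were seen, the junction list was no longer above chance in acetylated length (percentile 91.8), nor was it by highest signal value (86.4), nor in promoter regions with −log10 q of at least 5 (12 genes, percentile 97.2).

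Embryonic and regenerating muscle genes were not set apart from random lists, with 8 of 12 promoter regions (percentile 64.2) and 1740 bp (percentile 65.9). Within the list, the regulators Myf6 (9229 bp), Myod1 (7559 bp) and Myog (5671 bp), which also act in adult muscle, had wide regions, and the embryonic myosin Myh3, the perinatal myosin Myh8 and the fetal receptor subunit Chrng had none. All 14 genes of atrophy and proteolysis had a promoter region (6493.5 bp, percentile 100), led by the ubiquitin ligase genes Trim63 and Fbxo31 (10000 bp each) and the protease gene Capn3 (9309 bp). Of the genes secreted by muscle, 12 of 14 had one (percentile 96.9) with a median of 4349 bp (percentile 99.9). Their promoter regions were above random lists with the pooled list and with either replicate's list (percentiles 97.9 to 99.5) and with matching on promoter CpG count (98.2), and their length was within random lists at 25 kb (94.9) and by highest signal value (64.9). Sparc (8250 bp), Vegfa (7969 bp) and Angptl4 (6369 bp) led, and the hormone genes Fgf21 and Ostn had none.

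Heart genes were mostly bare. Of 18 cardiac genes 5 had a promoter region (3 in replicate 1 and 5 in replicate 2), against a median of 11 in random lists (percentile 0.255). The median acetylated length of the list was 0 bp, the lowest possible value. Percentile 3.15 was the lowest that a list of 18 genes could reach, so it could not be called below random lists. It was below those matched on promoter CpG count (0.690). The atrial and ventricular genes Myh6, Myl7, Tnnt2, Nppa and Nppb had 0 acetylated bp, as had the cardiac transcription factor genes Gata4, Nkx2-5 and Tbx20, the calcium release channel gene Ryr2 and the pacemaker channel gene Hcn4. Of these only Hcn4 differed in a single replicate, with a promoter region and 728 bp in replicate 2. Tnni3, cardiac troponin I, and Mybpc3, cardiac myosin-binding protein C, had 1023 and 497 bp in their windows and no promoter region. The members with one were Gja1, the gap junction protein of many tissues (10:56377330-56402513, 7636 bp), Actc1, cardiac actin (3434 bp, 950 in replicate 1 and 3592 in replicate 2), Myl4, the atrial and embryonic light chain (2659 bp), the potassium channel gene Kcnq1 (2156 bp) and Hand2 (275 bp, 0 in each replicate). Cardiac genes averaged 982 ± 1968 bp (SD, n = 18 genes), 7538.63 bp below fast genes (two-sided permutation test, p = 1e-05, the smallest possible, adjusted p = 3e-05). The difference was 7186.48 bp with the replicate 1 list and 7523.19 bp with the replicate 2 list.

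Markers of the other cells of a muscle were acetylated to differing degrees. Vascular and connective tissue lists stood above random lists in acetylated length. The endothelial list had 16 of 16 promoter regions and a median of 7191.5 bp, led by Egfl7, a secreted vessel protein (10000 bp), Eng, a TGF-beta coreceptor (9747 bp), and Erg, an endothelial transcription factor (9083 bp). The smooth muscle and pericyte list had 14 of 14 and 6047.5 bp, led by Des (9728 bp), which skeletal fibres also use, Pdgfrb (9112 bp) and Higd1b (8350 bp). The fibroblast and fibro-adipogenic list had 13 of 14 and 5846 bp, led by the proteoglycan gene Dcn (9644 bp), Gsn (9250 bp) and Pdgfra (8730 bp), and lacking Tcf21. Satellite cell markers, of the stem cells of muscle, had 13 of 14 and 4306 bp (percentile 99.8), led by Itga7 (9858 bp), Des and Heyl (7022 bp), and lacking Calcr, the calcitonin receptor of quiescent cells. The tenocyte list had 10 of 10 and 3993.5 bp (percentile 99.2), led by Scx, a tendon transcription factor (7436 bp), Egr1 (6727 bp) and Col12a1 (5599 bp). With the replicate 1 list alone the tenocyte list had a median of 2207.5 bp and was within random lists (percentile 92.4), as it was against random lists of genes that have a promoter region (percentile 92.7). In promoter regions the tenocyte list was within random lists with the pooled list, the replicate 2 list, −log10 q of at least 5 and promoters of 500 bp (9 genes in each, percentiles 96.7 to 97.1), and the satellite cell list was within lists matched on promoter CpG count (97.0). In the highest signal value near the start none of these 5 lists was above random lists (percentiles 28.3 to 71.6).

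Blood, fat and nerve sheath markers did not stand above random lists of all protein-coding genes. The macrophage and leukocyte list had 8 of 16 promoter regions (percentile 18.8) and 199 bp (percentile 9.03), with 0 bp in replicate 1 and 353 bp in replicate 2. Cd68, a lysosomal protein of macrophages (5310 bp), C1qb, a complement subunit (3345 bp), and Cd163, a scavenger receptor (2319 bp), led, and Ptprc, Adgre1 and Cx3cr1 had none. The adipocyte list had 5 of 12 (percentile 9.25) and 496.5 bp, with 180 bp in replicate 1 and 483.5 bp in replicate 2. Fabp4 (7889 bp), Car3 (7823 bp) and Lpl (7363 bp), which endothelium or muscle fibres also express, were at the top, and Adipoq, Plin1 and Lep had no promoter region. Against random lists of genes that have a promoter region, the 5 adipocyte genes with one lay above chance (median 7363 bp, percentile 99.75). The Schwann cell list had 7 of 12 (percentile 42.1) and 1287.5 bp, led by Pmp22 (10000 bp) and including Cnp (4362 bp), with none at S100b and Mag. In number of promoter regions, the leukocyte list lay above random lists matched on promoter CpG count (percentile 99.3).

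Lists of red cells and of tissues that the muscle should lack had fewer promoter regions than random lists. Each of these lists had a median acetylated length of 0 bp, the lowest possible value. Their percentiles (4.44 to 4.845) were the lowest that lists of their size could reach, so they could not be called below random lists. The neuron list was below lists matched on gene span (1.63) or on promoter CpG count (0.205). The erythroid list had 2 of 10 promoter regions (percentile 0.540), and its members included Klf1 with 1535 bp and Hba-a2 with 279 bp. No promoter region was found at Hbb-bs, Hbb-bt and Hba-a1, which is uncertain because the adult globin genes have near-identical copies. The neuron list had 2 of 12 (percentile 0.0750), with Camk2a, a kinase gene that also encodes a muscle anchoring protein (7210 bp), Stmn2 (2143 bp) and Slc17a7 (714 bp) leading and none at Rbfox3, Snap25 and Syt1. The hepatocyte list had 1 of 12 (percentile 0.0150), at Apoa2 (2794 bp), and none at Alb, Apoa1 and Ttr. It had 1 in replicate 1 and 0 in replicate 2. The pluripotency and germ line list had 1 of 12 (percentile 0.0150), at Dazl (1052 bp), with 357 bp at Nanog outside its promoter and no promoter region at Pou5f1, Nanog and Zfp42. In number of promoter regions, the erythroid and hepatocyte lists were no longer below chance against random lists matched on promoter CpG count (percentiles 54.8 and 8.08).

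Clock and stress genes were widely acetylated. All 16 clock genes had a promoter region, with a median of 6030 bp, led by Nr1d1, which encodes the repressor REV-ERB alpha (9908 bp), Per1 (9813 bp) and Dbp, an output factor of the clock (9214 bp). All 16 stress and immediate early genes had one at 5491.5 bp, led by the AP-1 subunit genes Jund (9140 bp), Junb (9103 bp) and Fosl2 (8531 bp). Both lists lay at percentile 100 for acetylated length. The 16 housekeeping genes all had one as well, at 3587 bp (percentile 99.6), led by Actb (9911 bp) and including Ppia (5348 bp). The housekeeping list fell within random lists matched on promoter CpG count (percentile 96.9) and within random lists of genes that have a promoter region (percentile 91.49). In number of promoter regions, all 3 lists fell within such matched lists (percentiles 95.9, 90.5 and 93.7).

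The gastrocnemius develops in the hindlimb, and some posterior Hox genes held wide acetylation in it while others held none. Hoxc10 (15:102966796-102971893), Hoxa9 (6:52223100-52231089) and Hoxa10 (6:52231197-52240854) were acetylated over all 10000 bp, Hoxc9 over 9702 and Hoxc11 over 8850. Of the regulators that set up the hindlimb bud, Pitx1 had 2860 bp, Isl1 687 bp and Tbx4 559 bp. The hindlimb list had 11 of 12 promoter regions (percentile 98.7) and lacked Hoxd11 (2:74679557-74687016). The forelimb and anterior list had 7 of 12 (percentile 42.1), with Hoxd3 (6623 bp) and Hoxa2 (5552 bp) at the top. Members without one included Tbx5, the forelimb regulator (5:119832668-119885219), Hoxb1, Hoxd1 and Otx2. Hindlimb genes averaged 5452.58 ± 4075 bp and anterior genes 2425.92 ± 2470 bp (SD, n = 12 genes each), a difference of 3026.67 bp (two-sided permutation test, p = 0.0400, adjusted p = 0.0400). The call did not hold up across all processing choices. In the same test p was 0.0525 with the pooled list (difference 2898.25 bp), 0.0695 with the replicate 2 list (2710.83 bp) and 0.188 with the 5′ end of the gene model alone (2062 bp). It was 0.0305 with the replicate 1 list, 0.0382 with −log10 q of at least 5, 0.0114 within 25 kb and 0.0143 by highest signal value. In long domains both lists stood above random lists, with 8 of 12 hindlimb genes (percentile 99.99) and 5 of 12 anterior genes (percentile 98.6), but neither did when only regions away from gene starts were stitched (percentile 37.9 each), and the anterior list did not without stitching (51.2). In promoter regions the hindlimb list was also within random lists matched on promoter CpG count (percentile 63.0) and, with the 5′ end alone, within random lists (95.7), and neighbouring Hox genes share regions, so members are not independent.

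Stitching joined the regions into 23088 domains, of which 1823 (7.90%) were long. The longest spread over Zbtb20, a zinc finger repressor (16:43349735-43639266, 154029 bp covered), Zbtb16, the zinc finger protein PLZF (9:48645663-48837765, 146608 bp), and Tns1, the focal adhesion protein tensin 1 (1:73902268-74098803, 146458 bp). The fourth held the starts of Neurl1b, Dusp1, a phosphatase of MAP kinases, Ergic1 and Atp6v0e (17:26414864-26700686, 142381 bp). The fifth lay in the body of Rad51b and held no protein-coding start (12:79707027-80018778, 137901 bp), and the sixth held Ahdc1, Wasf2, Gpr3, Cd164l2 and Map3k6 (4:133010627-133250788, 137436 bp). Then followed Col4a1 with Col4a2, the paired basement membrane collagens (8:11248877-11419493, 129993 bp), Nfib, a nuclear factor I protein (4:82383266-82616346, 129637 bp), Irf2bpl with Cipc, an inhibitor of the clock protein CLOCK (12:86768134-86975245, 122640 bp), and Sgms1, a sphingomyelin synthase (19:32121932-32390661, 120313 bp). Their ranks went down to 72 in replicate 1, at the Sgms1 domain, and to 96 in replicate 2, at the Rad51b domain.

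Long domains held 47.5% of all covered base pairs (56.1 Mb) and the starts of 3248 protein-coding genes. Of the long domains, 82.3% (1501) overlapped a long domain of replicate 1 and 94.0% (1714) one of replicate 2. Starts in long domains were most frequent among sarcomere (17 of 20), fast (16 of 20) and excitation-contraction coupling genes (14 of 20), against a median of 3 of 20 in random lists (percentile 100 each). Neighbouring members can share a domain, as the fast genes Tnni2 and Tnnt3 did. Random lists drew genes singly, so percentiles of lists with neighbouring members may be too high. Glycolysis had 13 of 20, muscle regulators 12, oxidative genes 9 and slow genes 8 of 16. Other lists were also above random lists: clock genes had 11 of 16, hindlimb genes 8 of 12, atrophy genes 9 of 14, stress genes 9 of 16 and housekeeping genes 6 of 16 (percentile 98.6). Cardiac genes had 1 of 18, at Tnni3. In all, 15 lists stood above random lists. When only regions away from gene starts were stitched, 5 did. The sarcomere, glycolysis and regulator lists then had 2 genes each (percentile 95.4), slow genes 1 (percentile 82.2) and oxidative genes 0 (percentile 31.0), all within random lists. That setting leaves out regions within 2500 bp of a start and then counts starts inside domains, so counts fall by construction.

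The X chromosome was the least acetylated of the chromosomes other than Y. It held 1456 regions, 8.51 per Mb, against 25.4 (chromosome 14) to 51.8 (chromosome 11) per Mb on the 19 autosomes. The ratio of X to the median autosome (33.7 per Mb) was 0.252 in the replicated list, 0.247 in replicate 1 and 0.261 in replicate 2. Of the genes on X, 42.0% had a promoter region, against 50.6% to 70.2% on the autosomes. Y held 2 regions, Y:10643350-10643894 (signal value 6.57) and Y:90744351-90744998 (4.21), although the mice were female.

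**Figure D4:**
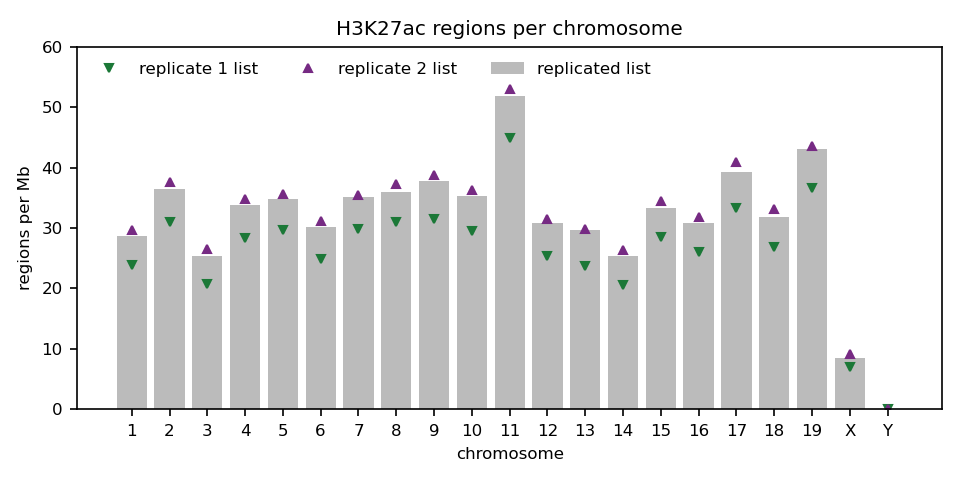
H3K27ac regions per Mb (vertical axis) on each chromosome (horizontal axis); bars give the replicated list and triangles each replicate. X lies at 8.51 regions per Mb in the replicated list and the autosomes lie between 25.4 and 51.8.

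Some binding motifs of muscle regulators were more frequent in distal regions than in their flanks, and others were not. The E-box CAGCTG, which MyoD and its relatives bind, was found in 31.6% of 61117 distal windows and 20.9% of flanking windows, a ratio of 1.51 (interval 1.48 to 1.54). Distal windows were richer in GC than their flanks (47.5% against 44.5%), and against shuffled sequence of the same composition the E-box ratio was 1.28 (1.25 to 1.30). The TEAD site had a ratio of 1.21 (1.17 to 1.25). These 2 ratios stayed above 1 with their intervals in all 8 alternatives. AP-1 sites had a ratio of 1.36 (1.316 to 1.404), ETS sites 2.23 (1.62 to 3.10), NRF1 sites 1.86 (1.22 to 3.001), glucocorticoid response elements 1.77 (1.11 to 3) and the core of the CTCF site, a mark of insulators, 3.41 (2.88 to 4.07). The interval of the glucocorticoid element reached or held 1 with the pooled list, with either replicate's list and with −log10 q of at least 5. The MEF2 site, bound by partners of MyoD, was barely above its flanks at 1.05 (1.01 to 1.08), and at 3.35 (3.18 to 3.55) against shuffled sequence. The intervals of the CArG box of SRF (0.985, 0.920 to 1.06), the NFI site (1.58, 0.974 to 2.65) and the ERR site (1.03, 0.935 to 1.13) held 1. That of NFI lay above 1 with the replicate 1 list (2.5, 1.43 to 4.75) and with −log10 q of at least 5 (1.75, 1.05 to 3.29). Among motifs of other tissues, the neuronal E-box had 1.04 (1.01 to 1.07), the HNF4 site 1.20 (1.06 to 1.36), the HNF1 site 0.556 (0.281 to 1.05) and the octamer of POU5F1 0.679 (0.630 to 0.729). Against shuffled sequence the neuronal E-box had 1.24 (1.20 to 1.28), near the values of the E-box CAGCTG and the TEAD site on that background. The HNF4 interval held 1 with the replicate 2 list (0.972 to 1.25) and against shuffled sequence (0.915 to 1.16). The HNF1 site matched 15 distal and 27 flanking windows, and its ratio lay between 0.154 (within 100 bp of the summit) and 1.07 (against shuffled sequence) over its alternatives. Within 100 bp of the summit the MEF2 ratio turned to 0.578, and the ratios of AP-1 (1.01), CTCF (0.984), glucocorticoid (0.818), ETS (1.27) and NRF1 sites (0.5) were no longer clear of 1. Against shuffled sequence the AP-1 ratio fell to 1.10 (1.06 to 1.13), the TEAD ratio was 1.24, the octamer turned to 1.09, the CArG box went to 0.679, the ERR site to 1.83, the glucocorticoid element to 2.71 and the NRF1 site, with 3 shuffled windows matched, to 18.

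**Figure D5:**
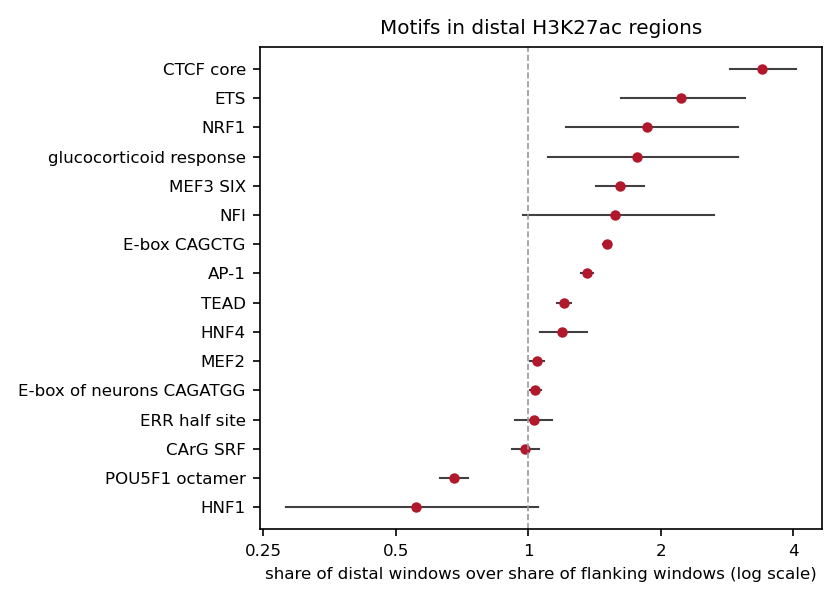
Ratio of the share of distal windows with a motif to the share of flanking windows (horizontal axis, log scale) for 16 motifs (vertical axis); points are ratios and lines cover the central 95% of 1000 bootstrap draws. The E-box CAGCTG lies at 1.51, CTCF at 3.41 and the POU5F1 octamer at 0.679.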

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

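Assembly gaps removed before shifting and random lists drawn from genes with a promoter region were chosen only after the results were seen; the other alternatives were fixed before the data were examined. The order of the pooled, replicate 2 and replicate 1 lists by size, the low density of the X chromosome and the differences of fast from slow and from cardiac genes kept their direction and their side of the threshold in every alternative run on them. For fast against slow genes p lay between 1e-05, the smallest possible, and 0.00950, and for fast against cardiac genes it was 1e-05 in each. The ratio of X to autosomes lay between 0.247 and 0.261 without 1 replicate. Unless the construction is named, the cause was not tested. Depth is unknown, so it was not possible to say which weak regions either replicate could have shown. The replicate 2 list was longer than the replicated list, and with −log10 q of at least 5 it was shorter (69803 against 71502 regions). No paired analysis was possible because there was 1 group.

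The overlap rule moved the shared percentages by construction. Of replicate 1 in replicate 2 they were 93.9% with 1 bp and 57.3% with 50% of both regions, and of replicate 2 in replicate 1 they were 64.0% and 46.8%. With 1 bp, the share found in both other pseudoreplicated lists was 17.9% and 100% in the lowest and highest of 10 bins of replicate 2 and 77.8% in the lowest bin of replicate 1. With −log10 q of at least 5, which changes the peaks and not the rule, the shared percentages were 95.6% of replicate 1 and 64.2% of replicate 2. Ranked by width, the lowest bin of the pooled list had 4.53% found in both other lists. The cause of these moves was not tested.

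Without 1 replicate, promoters took 17.6% to 21.2% of regions, exons 8.49% to 9.49% and intergenic sequence 27.3% to 28.6%, and median widths were 1455.5 to 1725.5 bp in promoters and 651 to 715 bp in distal regions. With −log10 q of at least 5, promoters took 20.6% and introns 41.0%, and distal regions had a median width of 904 bp and a signal value of 4.80. The pooled list gave introns 44.7% and a distal width of 676 bp. The wider promoter definition gave promoters 21.9%, introns 41.5%, intergenic sequence 27.9%, a promoter width of 1537 bp and a promoter signal value of 16.4. With gaps removed the excess at promoters was 5.06-fold.

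Lists below random lists in promoter regions numbered 5, and 3 with random lists matched on promoter CpG count. Lists above in acetylated length numbered 20, and 11 by highest signal value and 18 against genes with a promoter region. Those below numbered 0, and 1 with matching on gene span (the neuron list) and 2 with matching on CpG count (the neuron and cardiac lists). In the replicated list without matching, lists with a median of 0 bp already had the lowest percentile their size allowed. They could not be called below there. Counted over single lists and alternatives, 14 calls in promoter regions, 15 in acetylated length and 19 in long domains were lost, and 5, 4 and 14 were gained, none with a change of side. Long domains numbered 4051 without stitching, which splits domains by construction. Lists above random lists in long domains numbered 5 when only regions away from starts were stitched, which lowers the counts of starts in domains by construction. In the permutation test, the hindlimb and anterior lists differed by 2898.25 bp with the pooled list (p = 0.0525), by 2062 bp with the 5′ end of the gene model (p = 0.188) and by 2710.83 to 3001 bp without 1 replicate; p over its alternatives lay between 0.0114 and 0.188.

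Of motif ratios, the glucocorticoid element was no longer clear of 1 with the pooled list (1.45, interval 0.902 to 2.39), without replicate 1 (1.24, 0.782 to 1.95), without replicate 2 (1.63, 1 to 2.79) and with −log10 q of at least 5 (1.63, 1 to 2.8). Nor were HNF4 without replicate 1 (1.11) and the neuronal E-box without replicate 2 (1.03). NFI was clear of 1 without replicate 2 (2.5) and with −log10 q of at least 5 (1.75). Against shuffled sequence the ratios were 3.35 for MEF2, against 1.05 over its flanks, 0.679 for CArG and 1.83 for ERR, which became clear of 1, 1.03 for HNF4, which was no longer so, and 1.09 for the octamer, which had been below 1. Within 100 bp of the summit they were 0.578 for MEF2, which had been above 1, 1.01 for AP-1, 0.818 for the glucocorticoid element, 1.27 for ETS, 0.5 for NRF1, 0.984 for CTCF, 1.02 for the neuronal E-box and 0.154 for HNF1.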

Other observations

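The lists of this paragraph and the next, and the tests of gene density on X, of both explanations for the shorter replicate 1 list and of MEF2 sites in 200 bp flanks, were chosen only after the results were seen. The nuclear factor I genes Nfia, Nfib, Nfic and Nfix, which encode transcription factors that act in muscle and many other tissues, were all acetylated over 10000 bp around a start, and all 4 lay in long domains (percentile 100 in acetylated length among random lists). Of 17 Krüppel-like factor genes 16 had a promoter region (percentile 99.9), the exception being Klf17, with a median acetylated length of 6750 bp and 8 genes in long domains. Nfib, Nfix, Klf7 and Klf9 had already been seen among the strongest results, so these percentiles are not independent evidence. Of 11 muscle microRNA hairpins 6 lay within 1 kb of a region, against a median of 2 in random lists of microRNA genes (percentile 99.1) and 475 of all 2195 microRNA genes (21.6%). Mir1a-1, Mir1a-2, Mir1b, Mir133a-1 and Mir133a-2, of the families shared by skeletal muscle and heart, and Mir486 had such a region. Mir1b overlaps the Mir1a-2 locus on chromosome 18, and Mir133a-1 lies near it. Mir1a-1 and Mir133a-2 lie near each other on chromosome 2. Random lists drew hairpins singly, so neighbours count as separate members and the percentile may be too high. Mir206 and Mir133b, which are linked to satellite cells and slow muscle, and Mir208a, Mir208b and Mir499, which lie within myosin genes, had none.

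The 4 Hox clusters differed. The Hoxa genes had a promoter region at 11 of 11 with a median acetylated length of 5613 bp, the Hoxc genes at 7 of 9 with 4138 bp, the Hoxb genes at 6 of 10 with 3029 bp and the Hoxd genes at 5 of 9 with 296 bp. Of all 39 Hox genes 28 lay in long domains, and part of them had been seen in the lists of position genes. The difference between clusters was not tested, since neighbouring genes share regions. Olfactory receptor genes, which sensory neurons of the nose use, had a promoter region at 7 of 1133, against a median of 692 in random lists. Imprinted genes had one at 14 of 20 (percentile 78.8), with a median of 1057 bp (percentile 27.7). The 2 regions on Y were also found in replicate 2, and the first of them in replicate 1. Of non-overlapping 50 bp stretches, 5 of 10 in the first Y region and 2 of 12 in the second occurred also on other chromosomes.

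The X chromosome had few regions, and neither a low density of genes nor one of unique sequence accounts for all of this by itself. X had 1.54 regions per protein-coding gene against 2.54 to 5.77 on the autosomes. It had 16.7 regions per Mb outside masked repeats and unknown bases against 40.0 to 76.8. Masking is not the same as the places where reads can be put. Masked repeats and unknown bases together took 49.1% of X against 32.5% to 37.2% of the autosomes. The 2 corrections were not combined, so either or both may account for a part. Whether CpG-poor promoters play a part stays open: of 275 X genes in the upper 50% of promoter CpG count, 83.6% had a promoter region (Wilson interval 78.8% to 87.5%), just below the lowest autosome at 84.0%, which its interval holds, and this use of the interval was decided after the value was seen. Lower signal at each acetylated X promoter is a candidate for a part, since the median highest signal value of such genes was 22.3 (interval 19.9 to 23.9) against 29.1 to 34.0 on the autosomes. X also had fewer regions for each gene with a promoter region, 3.66 against 5.01 to 8.36, so the shortage was not of promoter regions alone. No biological explanation was tested, because the series held females only.

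Replicate 1 had fewer regions than replicate 2. Of the 32631 replicate 2 regions not shared with replicate 1, 89.7% lay in the lower 50% of signal values, with a median of 3.80 against 7.85 for shared regions, and 1 lay in the highest of 10 bins of signal value. Weaker recovery and a stricter call in replicate 1 cannot be told apart from other causes here: the rise of the shared percentage with signal value had been seen before, so this share could hardly have come out otherwise. Other cell types in the replicate 2 pool could not be told apart from chance: of 103 non-muscle cell type genes, 4 (among them Cd163, Lyz2 and Sox10) had a promoter region in replicate 2 alone, against a median of 2 and a central 95% of 0 to 6 in random lists (percentile 82.0), and 2 (Cd68 and Tnmd) in replicate 1 alone. No biological difference between the pools is given by the labels, and none was tested.

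MEF2 sites were scarce close to the summits of distal regions, at 0.578 of the flanks (interval 0.537 to 0.619) within 100 bp, although MEF2 proteins act at muscle enhancers. Flanks as rich in MEF2 sites, relative to their own base composition, are argued against in windows of the same 200 bp: flanks had 1.62 times the matches of their shuffled sequence (interval 1.52 to 1.73) and windows at the summit 2.11 times (1.92 to 2.34). In windows of 500 bp the values were 1.84 (1.76 to 1.92) and 3.35 (3.18 to 3.55). Base composition at the summits may contribute, since MEF2 sites within 100 bp stood above the shuffled sequence of the same windows and below the flanks. Summits may also lie beside the sites, as the ratio to the flanks was 1.19 (1.15 to 1.24) from 250 to 500 bp off the summit. The E-box CAGCTG had 1.62 within 100 bp (1.14 against shuffled sequence) and 1.30 in that outer ring, so this pattern did not hold for every muscle motif. AP-1 sites had 1.01 within 100 bp and 1.31 in the ring, CTCF sites 0.984 and 2.08, and TEAD sites 1.13 and 1.20. A higher ratio off the summit was thus not particular to MEF2. No biological explanation was tested.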
